A study of Mus musculus with 12 samples.

How the data were processed

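The deposited table holds whole-number counts per gene for 12 libraries, which the authors made from paired-end reads, and no normalized values. Per the labels' protocols, RNA was purified with oligo(dT) beads, fragmented and made into libraries with a dUTP-marked strand. The submitters' processing notes name the mm10 build, cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, DESeq2 and edgeR, without their roles or order. The counts may therefore be whole-number estimates from StringTie, and the annotation release and whether counting used the strand are not given in the sources used here. Overlapping and antisense genes, and genes with near-identical copies, are uncertain for that reason. RNA without a poly(A) tail enters such libraries only as carry-over, so its share can differ between preparations.

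Of 55401 gene IDs, 55141 matched a symbol, and the unmatched IDs took between 0.0126 and 0.0275% of counts. Coordinates and gene types came from GENCODE mouse release M21, which uses the same assembly as mm10. Groups came from the treatment given in the labels and replicate numbers from the sample titles.

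Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum of 10 counts, which left 21958, libraries were scaled by TMM, and a robust quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, which share 1 estimate of the spread (9 residual degrees of freedom, biological coefficient of variation 23.2%). P-values are two-sided and adjusted by the Benjamini-Hochberg method at 0.05. CPM values use TMM-scaled library sizes. Gene lists of pathways and cell type markers, 31 in all, were fixed before the data were examined and tested with camera in limma 3.58.1, with the preset correlation of 0.01 and with an estimated one, and with fry. With the estimated correlation and with directional fry, 0 lists were called in any comparison; the test of fry for change in either direction called 1, 6 and 9 lists in the order of the comparisons. The median, the mean and the camera direction differed in sign only for lists that camera did not call: camera and the median differed for 2, 7 and 3 lists.

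Htr6 and Atr were named in every comparison. Where fewer than 6 genes passed, the 10 with the smallest p, a mean of at least 1 CPM and a symbol that is not a predicted model were named as values. Of each list, up to 3 members that passed were named, otherwise at most 1 as a value. Sult1a1, Mertk, Col6a1 and Sox6 in the third comparison were named beyond that rule after their values were seen, to complete small counts. These rules and the alternatives were also set before the data were examined, except 3 alternatives chosen after seeing the data: the share of counts at CT010467.1 as a covariate, the fit without scramble saline replicate 4 and knockdown replicate 3, and protein-coding genes of at least 1 CPM only. Set beforehand were other scalings, filters and thresholds, DESeq2 1.42.0, limma voom with sample weights, the compared groups alone, the replicate number as a block, 1 surrogate variable from sva 3.50.0, and each library left out.

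The steps were tested on simulated counts with 200 changed genes drawn from the real means and library sizes. For knockdown against scramble with morphine, 21357 genes in the step, the test recovered 38.8% of genes changed by 0.5 on the log2 scale, 80.6% of those changed by 1 and 92.4% of those changed by 2. For morphine against saline, 21341 genes in the step, it recovered 41.8, 76.1 and 95.5%. For knockdown with morphine against scramble with saline, 21343 genes in the step, it recovered 28.8, 74.6 and 93.9%. Simulated genes varied independently and 200 were truly changed, so these percentages may overstate recovery in the real counts. A count of 0 calls therefore does not show an absence of change. Replicates of a group differed by more than sampling noise, and no pair of libraries within a group agreed closely enough to be the same library (chi-square per gene of at least 13.1); pairs from different groups were not compared in this way.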

Results

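RNA was measured in the medial prefrontal cortex of male mice after 2 weeks of extinction of a morphine-induced conditioned place preference, a test in which an animal learns to prefer a chamber paired with a drug and then loses that preference. Each of 3 groups had 4 libraries: a scramble virus with saline, the same scramble virus with morphine, and a virus that knocks down the serotonin receptor 5-HT6R with morphine. The viruses were adeno-associated. There was no group with the knockdown and saline. Total counts per library ran from 41483220 to 65739423. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical in part.

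Htr6, the gene of 5-HT6R (ENSMUSG00000028747, mm10 chromosome 4, 139061108 to 139075570, minus strand), was measured first because the virus targets it. It stood at 6.17 ± 1.60 CPM, counts scaled to library size (SD, n = 4) with scramble and saline, 5.22 ± 0.32 with scramble and morphine and 4.77 ± 0.76 with knockdown and morphine. The saline libraries of replicates 2, 3, 4 and 5 gave 5.45, 6.92, 4.35 and 7.98 CPM. The scramble morphine libraries of replicates 1, 3, 4 and 5 gave 5.30, 5.16, 4.82 and 5.58, and the knockdown libraries of replicates 1, 2, 3 and 5 gave 4.49, 5.30, 3.82 and 5.46. Between knockdown and scramble with morphine the log2 fold change was -0.13 (SE 0.18, edgeR adjusted p = 0.823), and an exact two-sided permutation test of log2 CPM over 70 assignments gave p = 0.314, adjusted 0.412 over 6 tests. The 95% interval of the fold ran from 0.685 to 1.22, so a lower Htr6 level than with scramble and morphine was not detectable in this tissue RNA and the gene does not check the labels. The log2 fold change was -0.04 without knockdown replicate 3 and -0.52 with the share of counts at the ribosomal RNA locus as a covariate (adjusted p = 0.973 and 0.933). The library labelled scramble saline replicate 4 had the lowest saline value and the library labelled knockdown replicate 5 the highest knockdown value. With these 2 labels exchanged, Htr6 in the saline and knockdown groups would not overlap (5.45 to 7.98 against 3.82 to 5.30 CPM). Exchanging these extremes moves the groups apart by construction. The exchanged knockdown group would still overlap scramble with morphine (4.82 to 5.58 CPM). The edgeR count for knockdown with morphine against scramble with saline would be 1603 genes in place of 3. Other values did not run that way: Lars2 took 0.179% of counts in that saline library, below the 0.243 to 0.289% of the other saline libraries, and 0.437% in that knockdown library, within the 0.301 to 0.587% of the other knockdown libraries. The share at the ribosomal RNA locus was likewise lowest of the saline libraries in the first (3.58%) and within the knockdown range in the second (5.12%). If Lars2 follows that share, it does not tell the group of a library, which was not tested. Ppp1r1b and Mrc1 separated the labelled groups without overlap, but these genes and Lars2 were named for a small p between labelled groups. The labels were kept. Between scramble with morphine and scramble with saline its log2 fold change was -0.24 (SE 0.18, edgeR adjusted p = 0.999), and 0.015 with the same covariate, an alternative chosen after seeing the data. Between knockdown with morphine and scramble with saline it was -0.37 (SE 0.18, edgeR adjusted p = 0.56), a fold of 0.773, and the exact permutation test gave p = 0.229, adjusted 0.412. Atr, a DNA damage checkpoint kinase (chromosome 9, 95857597 to 95951781, plus strand), stood at 14.6 ± 2.26, 12.9 ± 0.87 and 14.2 ± 0.86 CPM (SD, n = 4) in the same order of groups. Its log2 fold change between knockdown and scramble with morphine was 0.13 (SE 0.11, edgeR adjusted p = 0.668). It was -0.18 (SE 0.11, adjusted p = 0.999) for morphine against saline with scramble, and -0.04 (SE 0.11, adjusted p = 0.944) for knockdown with morphine against scramble with saline, where it turned to 0.04 without scramble saline replicate 2.

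Counts at the ribosomal RNA locus CT010467.1 (chromosome 17, 39846353 to 39848827, minus strand) took 4.57 ± 0.84% of a library with scramble and saline (SD, n = 4), 2.71 ± 0.29% with scramble and morphine and 6.46 ± 2.16% with knockdown and morphine. All 4 scramble morphine libraries lay below all libraries of both other groups. The exact two-sided permutation test gave p = 0.0286 against each of them, the smallest that 4 against 4 libraries allow, and 0.0981 after adjustment over 24 tests of library measures. The mitochondrial ribosomal RNAs took 0.432 ± 0.028% of counts with scramble and morphine and 0.592 ± 0.065% with the knockdown (SD, n = 4).

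**Figure D1:**
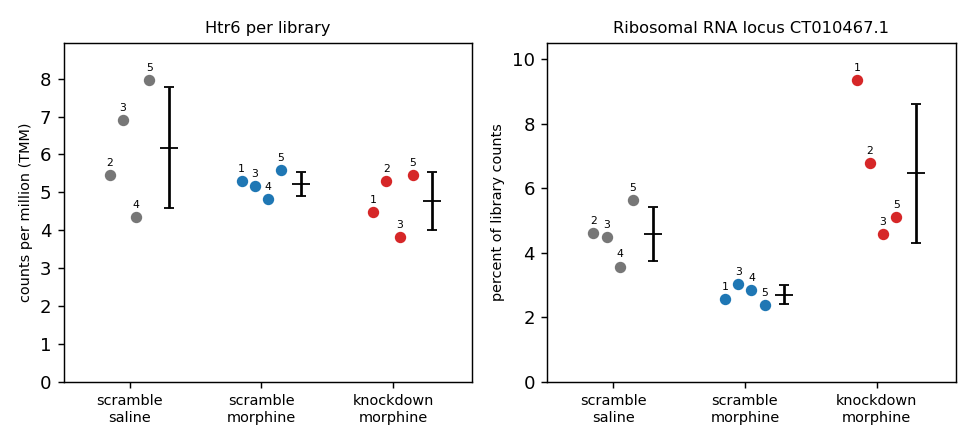
Each point is 1 library, numbered by replicate, with the group mean and SD in black. Left, Htr6 in CPM, where the 3 groups overlap; right, the share of library counts at CT010467.1 in percent, where the scramble morphine libraries lie between 2.38 and 3.04%.

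The first comparison asked what morphine left behind in mice with the scramble virus. Genes induced by glucocorticoids stood higher with morphine than with saline, with Zbtb16, a zinc finger transcription factor, at 61.7 ± 5.95 against 46.4 ± 1.16 CPM (SD, n = 4) and a log2 fold change of 0.41 (SE 0.07). Plin4, a lipid droplet protein, had a log2 fold change of 0.79 (SE 0.20), and Tsc22d3, also known as Gilz, one of 0.50 (SE 0.14). These 3 genes and Sult1a1, at 0.66 (SE 0.19), passed when adjusted over the list alone, and 0 passed over all genes. The list's median log2 fold change was 0.20 over 25 genes, 19 of them above 0. Camera with its preset correlation called it higher (adjusted p = 5.25e-09), while the adjusted p = 0.538 with an estimated correlation. With the mean of astrocyte markers as a covariate, a test chosen after seeing the data, the list's median was 0.0847.

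No single gene passed in this comparison. The edgeR quasi-likelihood test called 0 of 21958 genes at a Benjamini-Hochberg adjusted p under 0.05, with 765 genes at an unadjusted p under 0.05 where chance gives 1098. DESeq2 called 6 genes, 3 higher and 3 lower, among them Zbtb16 (adjusted p = 0.00724) and Fmo2 (adjusted p = 0.036), and limma voom called 0. Among the 10 named genes with the smallest p, Fmo2, a flavin monooxygenase, had a log2 fold change of 0.85 (SE 0.18), Tfcp2l1 of 0.51 (SE 0.11), Frmpd1 of 0.48 (SE 0.12) and Prodh, proline dehydrogenase, of 0.44 (SE 0.12). Below 0 were Tfrc, the transferrin receptor, at -0.33 (SE 0.08), the zinc transporter Slc39a7 at -0.48 (SE 0.12) and Gk5 at -0.69 (SE 0.20). The smallest adjusted p of the comparison was 0.859.

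Markers of astrocytes also stood higher with morphine: all 23 lay above 0, with a median log2 fold change of 0.19 and 0 genes passing over the list alone. Markers of pericytes, smooth muscle and meningeal fibroblasts had a median of 0.38, with 26 of 30 above 0 and 0 passing. Camera called both higher with its preset correlation (adjusted p = 3.56e-11 and 2.87e-10), and both had an adjusted p = 0.658 with an estimated correlation. Members of these lists vary together (estimated correlation 0.475 and 0.416) and are not separate observations. In the same libraries the share of counts at CT010467.1 was 2.71% with morphine against 4.57% with saline, and protein-coding genes took 93.1 against 91.1% of counts, each without overlap between these groups. The interferon response list had all 42 genes below 0, median -0.46 (camera adjusted p = 6.06e-07, and adjusted p = 0.903 with an estimated correlation). Its genes also vary together (estimated correlation 0.794). Without scramble saline replicate 4 camera gave the opposite direction, with an adjusted p = 0.926. The other calls with the preset correlation were mitochondrially encoded genes and heat shock genes, higher with medians of 0.09 and 0.05, and blood markers, ribosomal proteins and immediate early genes, lower with medians of -0.73, -0.07 and -0.12. Blood markers had an adjusted p = 0.839 and each of the other 4 an adjusted p = 0.903 with an estimated correlation. Even with the preset correlation, omitting 1 library ended the camera call of blood markers (scramble saline replicate 3, adjusted p = 0.241) and ribosomal proteins (scramble saline replicate 4, 0.755; scramble morphine replicate 4, 0.274). The same held for immediate early genes (scramble saline replicates 2 and 3, 0.0694 and 0.78; scramble morphine replicates 1 and 5, 0.448 and 0.734) and for heat shock genes (scramble saline replicates 2, 3 and 5 and scramble morphine replicates 3, 4 and 5, between 0.0504 and 0.186).

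The second comparison asked what the 5-HT6R knockdown changed in mice given morphine. Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, stood at 50.0 ± 4.57 CPM with the knockdown and 79.3 ± 7.35 with scramble (SD, n = 4), a log2 fold change of -0.66 (SE 0.10), lower in 4 of 4 libraries. It passed when adjusted over the list alone in the cAMP and striatal neuron lists, and its edgeR adjusted p over all genes was 0.115. The interneuron neuropeptide genes Sst and Npy passed as lower when adjusted over the list alone, with log2 fold changes of -0.41 (SE 0.09) and -0.78 (SE 0.19). Mrc1, a marker of macrophages at brain borders, passed as higher by the same measure at 1.01 (SE 0.19), and Siglech, a microglial gene, as lower at -0.49 (SE 0.14). Atf3, a stress-induced transcription factor, was at 1.57 (SE 0.37) and Ier5 at -0.24 (SE 0.07), both passing adjusted over the list alone. So did Crebbp at 0.26 (SE 0.07), Rims3 at 0.41 (SE 0.09), Pdgfra at 0.20 (SE 0.06) and Sox6 at 0.33 (SE 0.10). Apart from Ppp1r1b, the edgeR adjusted p of these genes over all genes lay between 0.239 and 0.289.

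Over all genes, the edgeR quasi-likelihood test called 0 of 21958, with 2643 at an unadjusted p under 0.05 where chance gives 1098. DESeq2 called 158 genes, 56 of them lower, and limma voom called 0. Without knockdown replicate 5 the edgeR count was 375, of which 216 were higher and 159 lower, and without scramble saline replicate 4, knockdown replicate 3, knockdown replicate 2 or scramble saline replicate 5 it was 4, 2, 1 and 1. Among the named genes with the smallest p were ribosomal RNA and other abundant RNA: Rn7sk, the 7SK RNA, at 1.53 (SE 0.28), CT010467.1 at 1.33 (SE 0.22), mt-Rnr1 at 0.55 (SE 0.09), mt-Rnr2 at 0.50 (SE 0.10) and Lars2, a mitochondrial leucyl-tRNA synthetase, at 1.44 (SE 0.20). With the share of counts at CT010467.1 as a covariate, an alternative chosen after seeing the data, Rn7sk was at -0.03. Nav3 was at 0.40 (SE 0.08), Aldh1b1 at -0.82 (SE 0.16) and C1qbp at -0.36 (SE 0.07). Without knockdown replicate 5 these 8 genes, Ppp1r1b and Mrc1 passed in edgeR, with Ppp1r1b at an adjusted p = 0.0162, and all 10 passed in DESeq2. Atf3 and Rims3 passed in the same settings, with an edgeR adjusted p of 0.0249 and 0.0162 without that library. Ppp1r1b also passed without scramble saline replicate 4 or 5 (adjusted p = 0.0291 and 0.0472), as did mt-Rnr1 and Lars2 without scramble saline replicate 4 (0.0291 each) or knockdown replicate 3 (0.0307 and 0.0189).

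Nuclear genes of the mitochondrial respiratory chain stood lower with the knockdown, 48 of 52 below 0 with a median log2 fold change of -0.15, as did markers of oligodendrocytes and myelin, all 24 below 0 with a median of -0.32. No member of either list passed over the list alone. Camera called both lower with its preset correlation (adjusted p = 2.48e-10 and 2.8e-10), and both had an adjusted p = 0.83 with an estimated correlation. Members of these lists vary together (estimated correlation 0.359 and 0.711) and are not separate observations. The same knockdown libraries had the higher share of counts at CT010467.1, 6.46% on average against 2.71% with scramble. Markers of cortical excitatory neurons (median -0.16) and interneurons (median -0.13) were also called lower with the preset correlation, each with an adjusted p = 0.83 with an estimated correlation. Markers of endothelium, and of pericytes and meningeal fibroblasts, were called higher with medians of 0.23 and 0.20, as were reactive glia genes at 0.26, mitochondrially encoded genes at 0.11 and ribosomal proteins at 0.07. Each of these 5 lists had an adjusted p = 0.967 with an estimated correlation. With the preset correlation, the calls of the respiratory chain, myelin and excitatory neuron lists held with each library left out. Scramble morphine replicate 4 ended the camera calls of interneurons (adjusted p = 0.0929), endothelium (0.0697), pericytes and meningeal fibroblasts (0.126), reactive glia (0.275) and ribosomal proteins (0.46) when omitted. So did scramble morphine replicate 5 and knockdown replicates 1 and 3 for interneurons (0.0578, 0.103 and 0.0638) and reactive glia (0.0884, 0.576 and 0.0638), and for ribosomal proteins (0.114, 0.576 and 0.0738). Knockdown replicate 1 did so for endothelium (0.0792), and knockdown replicate 2 for ribosomal proteins (0.0704) and mitochondrially encoded genes (0.125).

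The lists that follow the study's title were not called in this comparison. ATR checkpoint genes had a median log2 fold change of 0.01 over 53 genes and 0 passing over the list alone, and primary cilium genes had -0.04 over 95 genes and 0 passing. Serotonin receptor and handling genes had a median of -0.03 over 19 genes and ciliary receptor genes 0.05 over 20, again with 0 passing. Their camera adjusted p was 0.93, 0.286, 0.375 and 0.93, and the test lay below 0 for the ATR list and above 0 for ciliary receptors, whose mean was -0.04. These lists were chosen from the study's own title and are not independent evidence of a direction. Hedgehog, opioid, mTOR, glutamate and GABA lists had 0 genes passing over the list alone, with camera adjusted p of 0.93, 0.942, 0.942, 0.93 and 0.93. Camera also did not call synaptic vesicle, cAMP, immediate early or glucocorticoid-induced genes (0.93 each), interferon response genes (0.358) or heat shock genes (0.133). Among markers it did not call astrocytes (0.0818), striatal projection neurons (0.663), oligodendrocyte precursors (0.484), microglia and macrophages (0.286), ependyma and choroid plexus (0.942 each) or blood (0.285).

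The third comparison set the knockdown with morphine against scramble with saline, where virus and drug differ together. It held the 3 calls of the data, all higher: Plin4 rose from 5.97 ± 0.71 to 15.2 ± 3.00 CPM (SD, n = 4), Fmo2 from 3.49 ± 1.0 to 8.19 ± 0.54, and Zbtb16 from 46.4 ± 1.16 to 64.8 ± 4.08. Their log2 fold changes were 1.35 (SE 0.20), 1.23 (SE 0.18) and 0.48 (SE 0.07), each with an edgeR adjusted p = 0.0489. In all 4 knockdown libraries each gene lay above all 4 saline libraries. Plin4 lies on chromosome 17 (56100591 to 56109803), Fmo2 on chromosome 1 (162874317 to 162898726) and Zbtb16 on chromosome 9 (48654297 to 48836222).

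**Figure D2:**
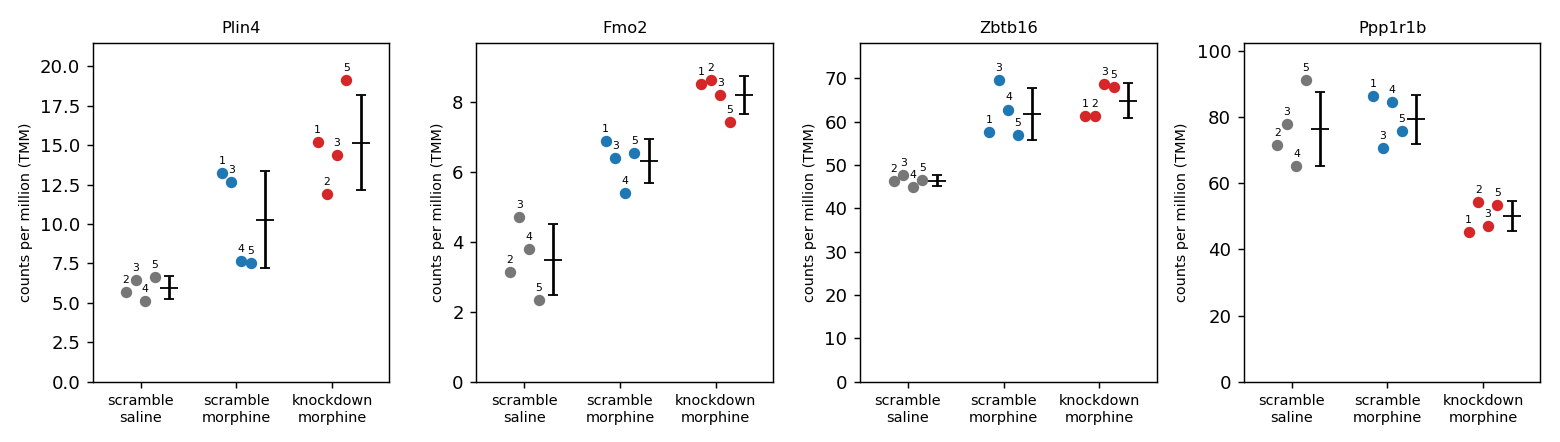
Each point is 1 library, numbered by replicate, in CPM from 0, with the group mean and SD in black. Plin4, Fmo2 and Zbtb16 lie lowest in the scramble saline libraries, and Ppp1r1b lies lowest in the knockdown libraries, between 45.2 and 54.3 CPM.

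These calls lay at the edge of the threshold. DESeq2 called 147 genes, 97 higher and 50 lower, among them Plin4, Fmo2 and Zbtb16, and limma voom called 0; 2052 genes had an unadjusted p under 0.05 in edgeR. The edgeR count fell to 0 without scramble saline replicate 2, 4 or 5, scramble morphine replicate 1, 3 or 5, or knockdown replicate 1, 2 or 3, where the adjusted p of Plin4, Fmo2 and Zbtb16 lay between 0.0654 and 0.231. It was also 0 with library totals as the only scaling and with the share of counts at CT010467.1 as a covariate (chosen after seeing the data), where the log2 fold changes of Plin4 and Fmo2 lay between 1.18 and 1.31 and those of Zbtb16 at 0.44 and 0.50. Fitted on the compared groups alone, 5 genes passed, with Plin4 but neither Fmo2 (adjusted p = 0.184) nor Zbtb16 (0.0581) among them. With all groups fitted, the count was 1, Fmo2, without scramble saline replicate 3, and was 7 without scramble morphine replicate 4 and 55 without knockdown replicate 5. The next named genes by p were Ppp1r1b at -0.61 (SE 0.10), Mrc1 at 1.16 (SE 0.19), Tfcp2l1 at 0.64 (SE 0.11), Prelp at 1.11 (SE 0.18), Postn at 1.14 (SE 0.20), Rprm at -0.77 (SE 0.14) and Nwd1 at 0.38 (SE 0.07), none passing over all genes. Without knockdown replicate 5, Ppp1r1b, Mrc1, Tfcp2l1 and Postn (adjusted p = 0.0415 each) and Prelp (0.0364) passed in edgeR, and Mrc1 did so without scramble morphine replicate 4 (0.033).

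Markers of pericytes, smooth muscle and meningeal fibroblasts stood furthest apart in this comparison, with a median log2 fold change of 0.69 and 28 of 30 above 0. Adjusted over the list alone, 14 were higher, among them Myl9 at 0.72 (SE 0.15), Pdgfrb at 0.38 (SE 0.10) and Col1a2 at 0.82 (SE 0.20), and Col6a1 was lower at -0.56 (SE 0.17). Camera called the list higher (adjusted p = 1.33e-19, and adjusted p = 0.259 with an estimated correlation). Its members vary together (estimated correlation 0.403). The share of counts at CT010467.1 was 6.46% against 4.57% in these groups, which overlapped. Mitochondrially encoded genes were higher in 11 of 13 over the list alone, among them mt-Nd2 at 0.26 (SE 0.06), mt-Nd4 at 0.21 (SE 0.06) and mt-Nd3 at 0.23 (SE 0.06). These genes vary together (estimated correlation 0.699) and are not separate observations. Their share of library counts overlapped between these groups, at 3.54 to 4.18% against 3.58 to 3.76%. The exact permutation test of that share gave p = 0.143, adjusted 0.245 over 24 tests. Glucocorticoid-induced genes had 2 higher over all genes, Plin4 and Zbtb16, and 5 over the list alone, with Xdh at 0.71 (SE 0.17), Sult1a1 at 0.80 (SE 0.19) and Mertk at 0.37 (SE 0.09). Both of these lists were called by camera, with an adjusted p = 0.314 with an estimated correlation. Markers of cortical excitatory neurons were called lower (adjusted p = 0.259 with an estimated correlation), and Syt6 at -0.79 (SE 0.21), Neurod2 at -0.24 (SE 0.07) and Fezf2 at -0.39 (SE 0.12) passed over the list alone, Syt6 also over all genes without knockdown replicate 5 (edgeR adjusted p = 0.0489). Myelin markers and the nuclear respiratory chain were called lower, with medians of -0.33 and -0.11, and heat shock genes higher with a median of 0.11, each with an adjusted p = 0.618 with an estimated correlation. Reactive glia genes, astrocyte markers and endothelial markers were called higher and the interferon list lower, each with an adjusted p = 0.893 with an estimated correlation. The interferon direction again turned without scramble saline replicate 4 (camera adjusted p = 0.145), and its call ended without knockdown replicate 2 or 5 (0.55 and 0.524). Camera calls with the preset correlation also ended for astrocytes without scramble saline replicate 4 or knockdown replicate 5 (0.795 and 0.298) and for endothelium without scramble saline replicate 4, knockdown replicate 1 or knockdown replicate 3 (0.532, 0.515 and 0.132). They ended for reactive glia without knockdown replicate 1 (0.317) and for heat shock genes without knockdown replicate 2 (0.0902).

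**Figure D3:**
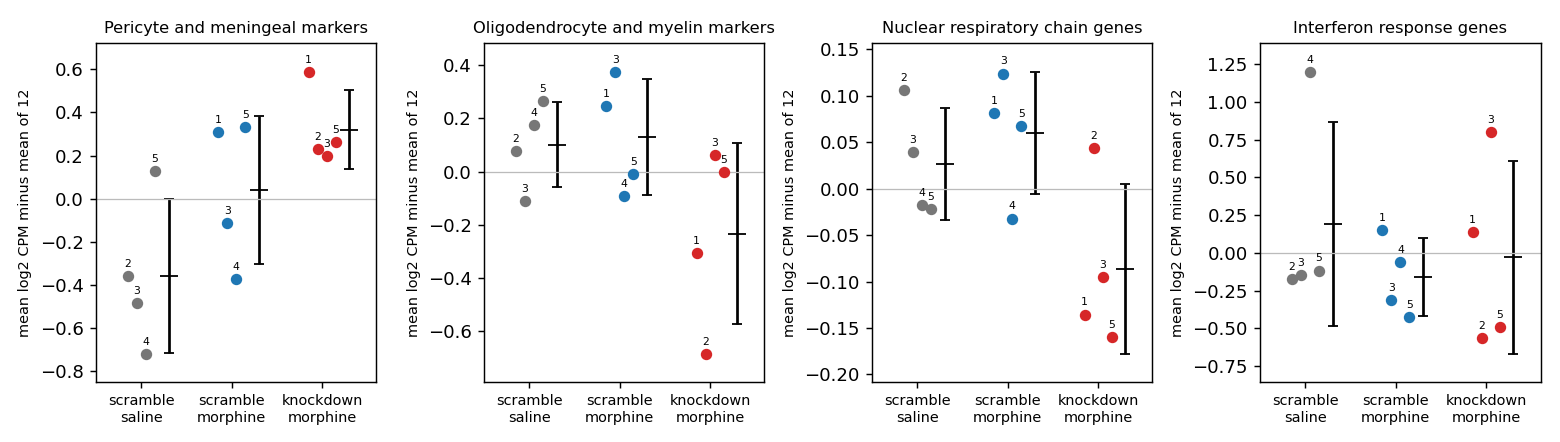
Each point is the mean log2 CPM of a gene list in 1 library minus its mean over all 12, numbered by replicate, with the group mean and SD in black, for pericyte and meningeal markers, myelin markers, the nuclear respiratory chain and interferon response genes. The interferon genes lie at 1.20 in scramble saline replicate 4 and at 0.80 in knockdown replicate 3.

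The last question was whether the knockdown moved genes against the direction of morphine. Across 21958 genes, which are not independent replicates, the log2 fold changes of both comparisons had a Pearson correlation of -0.53 and a covariance of -0.119. Both use the scramble morphine libraries, with opposite signs, so a negative value arises with no effect at all: 50 simulated sets of unchanged groups gave a correlation of -0.50 ± 0.02 (SD) and a covariance of -0.106 ± 0.00671 (SD). Over genes with a mean of at least 1 CPM the correlation was -0.351, less negative than all 50 simulated values (-0.502 ± 0.0523, SD, up to -0.361). Leaving out single libraries moved it between -0.525 and -0.182. Simulated genes varied independently, with the same spread in every group. In the data, chi-square per gene was 16.1 to 24.2 between scramble morphine libraries and 42.1 to 97.8 between knockdown libraries. The simulated values therefore do not decide whether both effects run with or against each other. The observed covariance differed from the simulated mean by -0.0137 over all genes, but by 0.00976 in the other direction over genes with a mean of at least 1 CPM, where it was -0.0257 against a simulated -0.0354 ± 0.00716 (SD). The covariance over all genes was -0.267, -0.234, -0.222 and -0.252 without scramble morphine replicate 1, 3, 4 or 5, and over genes of at least 1 CPM it was -0.053 without scramble morphine replicate 1, -0.0142 without scramble saline replicate 4 and -0.015 without knockdown replicate 1. No unchanged groups were simulated for these smaller sets, so how far they lie from chance was not tested. When the scramble morphine libraries were split so that the comparisons shared none, all 6 ways gave correlations between -0.16 and -0.116 over all genes, where simulated unchanged groups, whose genes vary independently, gave -0.0256 ± 0.0229 (SD). Over genes with a mean of at least 1 CPM the 6 ways gave between -0.138 and -0.00465, against a simulated -0.0575 ± 0.0691 (SD). No gene was called in both comparisons, as each had 0 calls, so the overlap of independent lists is also 0.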

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

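Tests of an astrocyte share, 1 saline library, immune cells and other sample splits were chosen after the results they bear on had been seen. Those of RNA without a poly(A) tail, of ribosome biogenesis and of the time of day were set before. Bootstrap intervals in this section were drawn over genes, not libraries, so they leave out the spread between libraries.

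Interferon response genes stood apart in scramble saline replicate 4, whose list score of 1.20 lay far from the -0.18 to -0.12 of the other saline libraries, and they were also high in knockdown replicate 3. More immune cells in these libraries is a candidate explanation. The 53 markers of microglia, macrophages, blood and lymphocytes outside the interferon list rose by only 0.0869 of the rise of that list, averaged over both libraries, which argues against it. An infection or another immune stimulus in these samples was not tested and stays open.

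The other values that lay far from the rest of their group are given without explanation. In scramble saline replicate 4 they were Prodh at 17.6 CPM, mt-Rnr2 at 2697 CPM and the mitochondrial ribosomal RNA share at 0.446%. Scramble saline replicate 2 had a microglia and macrophage score of -0.17, and scramble saline replicate 5 had Col1a2 at 39.7 CPM. In scramble morphine replicate 4 they were Slc39a7 at 54.7 CPM, Olig2 at 18.9 CPM and an astrocyte score of -0.061. Scramble morphine replicate 1 had Tfrc at 79.8 CPM and scramble morphine replicate 5 had Sox6 at 24.8 CPM. Knockdown replicate 3 had a mitochondrial ribosomal RNA share of 0.494%, and knockdown replicate 5 had Neurod2 at 61.8 CPM. Over 273 groups of values examined, 13 stood out in this way, where chance gives about 13.7.

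CT010467.1, mt-Rnr1, mt-Rnr2 and Rn7sk, all of them RNA that is not messenger RNA, were higher in the knockdown than in the scramble morphine libraries. Weaker removal of RNA without a poly(A) tail in library preparation is one candidate explanation. Over 141 other genes, taken as lacking such a tail by gene type or histone symbol, the median log2 fold change was 0.0716 (bootstrap 95% interval -0.0058 to 0.169). Whether each of these RNAs had a tail was not checked. CT010467.1 was at 1.33. That set was mixed: 37 histone genes had a median of -0.43 and 104 small nuclear, small nucleolar and mitochondrial transfer RNA genes one of 0.13. Rn7sk, which is not ribosomal RNA and was outside that set, was at 1.53. The set therefore does not decide the question, and carry-over stays open, of ribosomal RNA alone or with other RNA. A biological alternative is more ribosomal RNA made together with its machinery. The 36 genes of RNA polymerase I and ribosome biogenesis did not run that way, with a median of -0.0653 (interval over genes -0.11 to -0.00339). That interval leaves out the spread between libraries, so it does not exclude this alternative. The scramble morphine share of counts at CT010467.1 was also below that with saline (2.71 against 4.57%). Between knockdown and saline that share overlapped (exact permutation p = 0.171, adjusted 0.274 over 24 tests). Which group stands apart is therefore not settled. The knockdown itself stays open as an untested source.

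Glucocorticoid-induced genes were higher with morphine than with saline. Scramble saline replicate 4 alone does not account for it, as the median was 0.158 without that library against 0.201 with it. More astrocyte RNA in the morphine libraries may account for part of it: with the mean of 22 astrocyte markers as a covariate the median fell to 0.0847, a drop whose bootstrap 95% interval of 0.0258 to 0.334 leaves open how large that part is. A different time of day at collection also stays open. Clock genes of the Per and Dbp phase minus those of the Bmal1 phase gave -0.213 (bootstrap 95% interval -0.345 to -0.0293), from only 10 and 4 genes. Their medians were -0.104 and 0.109, and the test counted a difference in either direction, so it did not use the direction. Per1 was left out because its values had been seen and it is also in the glucocorticoid list. Morphine itself stays open too.

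For morphine against saline and for knockdown against scramble with morphine, the test called 0 genes, so all 35 of 35 splits of the same 8 libraries into 4 and 4 give at least as many by construction, and this count says nothing about chance (highest other 18 and 1). The other counts were each matched by at least 1 other split, so chance could not be excluded for them; the numbers of splits that follow include the labelled one. At an unadjusted p under 0.05, 4 splits gave as many as the 765 genes for morphine against saline (highest other 1266) and 3 gave as many as the 2643 genes for knockdown against scramble with morphine (highest other 2982). For knockdown with morphine against scramble with saline, 2 splits gave as many as the 3 calls and 5 as many as the 2052 genes at an unadjusted p under 0.05 (highest other 4591).

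The highest other split in that last comparison called 1603 genes against 3 for the labelled split. It was picked as the largest of 35, and how often the largest reaches such a count with no group difference was not tested. That split exchanged the libraries labelled scramble saline replicate 4 and knockdown replicate 5. Exchanged in this way, the Htr6 levels of both groups would not overlap, with 5.45, 5.46, 6.92 and 7.98 CPM against 3.82, 4.35, 4.49 and 5.30. The second set would still overlap the scramble morphine libraries (4.82 to 5.58 CPM), and the exchanged libraries held the lowest saline and the highest knockdown value. At an unadjusted edgeR p under 0.05, knockdown replicate 5 exchanged with saline replicate 2, 3 or 5 gave 1393, 1826 and 1438 genes. The labelled split gave 2052. Exchanged with scramble morphine replicate 1, 3, 4 or 5, it gave 2721, 2407, 2982 and 2359, where the labelled split of those groups gave 2643. Its limma voom sample weight, 0.397, was the lowest of all 12 libraries. On the first principal component of all 12 libraries, which held 15.1% of the variance, scramble saline replicate 4 lay at 30.3. The other saline libraries lay between -17.4 and -6.96, and knockdown replicates 1, 2 and 3 at 65.5, 31.7 and 32.8. Knockdown replicate 5 lay at -24.8, outside the other saline libraries and within the -39.7 to -4.32 of scramble morphine. On the second component (12.3%), scramble saline replicate 4 lay at 20.1 and knockdown replicates 1, 2, 3 and 5 at 15.9, -84.4, 21.5 and 4.21. The other saline libraries lay there between 3.81 and 15.9. Other values did not run that way. The Lars2 share was 0.179% in scramble saline replicate 4, further from the knockdown libraries than the 0.243 to 0.289% of the other saline libraries, and 0.437% in knockdown replicate 5, and their mitochondrial ribosomal RNA shares were 0.446 and 0.620%. Their shares at CT010467.1 were 3.58 and 5.12%. Carry-over stays open for ribosomal RNA, so these shares may reflect preparation and not group. Lars2 did not follow CT010467.1 fully: scramble saline replicate 5 had 5.63% at CT010467.1 and 0.289% at Lars2. Ppp1r1b (65.2 and 53.5 CPM), Mrc1 (4.97 and 10.6 CPM) and Zbtb16 (44.9 and 67.9 CPM) lay on their labelled sides and would overlap after an exchange, but they and Lars2 were named because they differ between the labelled groups. Ppp1r1b passed in edgeR between knockdown and scramble with morphine without knockdown replicate 5, though not with all 12, so its level in that library had no part in that call. It also passed without scramble saline replicate 4, but that library is in neither group of this comparison, so that pass does not bear on an exchange. An exchange of these samples is a candidate explanation with values on both sides and stays open. So does another difference between these libraries, or a difference of knockdown replicate 5 alone. The labels were kept throughout.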

How the results depend on the processing

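Alternatives were planned except the 3 described as chosen after seeing the data, and the cause of a change was not tested unless stated. For morphine against saline with scramble virus, the count of 0 genes became 6 with DESeq2, 1 with only the compared groups fitted and 1 with the replicate block, and leaving out each library kept it at 0. For knockdown against scramble with morphine, the count of 0 became 158 with DESeq2, 2 with no filter, 2 with the replicate block, 1 with a surrogate variable and 5 without the 2 libraries with high interferon genes (chosen after seeing the data); leaving out single libraries gave 0 to 375. For knockdown with morphine against scramble with saline, the count of 3 became 147 with DESeq2, 15 with a surrogate variable, 5 with no filter, each with all of the 3 among them, and 5 with only the compared groups, of which 1, Plin4, was among the 3. It became 0 with library totals only, limma voom, the replicate block, the ribosomal RNA share as a covariate and without the 2 interferon libraries (the last 2 chosen after seeing the data). In these 5 settings the log2 fold changes stayed at 1.20 to 1.31 for Plin4, 1.18 to 1.31 for Fmo2 and 0.44 to 0.50 for Zbtb16, with adjusted p between 0.0538 and 0.399. Leaving out single libraries gave 0 to 55.

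The replicate numbers were not used as pairs, because the labels give them no shared origin and not every pair with the same number deviated together: over 9 such pairs the correlation of deviations ran from -0.06 to 0.27, with 5 over 0.1. The pairs over 0.1 were those of numbers 1, 2 and 5 (0.16 to 0.27), while those of numbers 3 and 4 lay between -0.06 and 0.07. In the data, 8 of 12 libraries correlated best with their own number, although most libraries they could match carried another number. The count expected by chance was not worked out. A structure shared by part of the numbers therefore stays open. The main test left it out, and the calls of the third comparison did not hold with the replicate block.

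The 9, 9 and 11 lists called by camera became 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with directional fry, and 1 with mixed fry for morphine against saline. Leaving out single libraries gave 6 to 12, 6 to 11 and 9 to 14 lists. The interferon list turned direction without scramble saline replicate 4, with adjusted p of 0.926 and 0.145, in ranges over single omissions of 3.17e-10 to 0.926 for morphine against saline and 5.53e-10 to 0.55 for the third comparison. Of single genes, Htr6 turned to 0.015 for morphine against saline and Rn7sk to -0.026 for the knockdown with the ribosomal RNA share as a covariate, and Atr turned to 0.045 for the third comparison without scramble saline replicate 2 (range -0.114 to 0.045). For knockdown against scramble with morphine, Htr6 lay between -0.52 (ribosomal RNA share as a covariate) and -0.03 (without the 2 interferon libraries) over all alternatives run, against -0.13, and passed in none (adjusted p 0.549 to 0.974). The correlation of both effects, -0.53, became -0.40 with a filter of 1 CPM in 4 libraries, and -0.121, -0.121, -0.116, -0.159, -0.117 and -0.160 in the 6 splits of the shared libraries, whose construction removes the shared values. Leaving out single libraries gave -0.67 to -0.45. Of simulated genes changed by 0.5 on the log2 scale, 38.8% were recovered for knockdown against scramble with morphine. Those genes varied independently, so recovery in the real counts may be lower.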

Other observations

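Markers of oligodendrocyte precursors did not move as 1 group between knockdown with morphine and scramble with saline. Adjusted over the list alone, Olig2 was lower at a log2 fold change of -0.34 (SE 0.09), Pcdh15 at -0.31 (SE 0.09) and Lhfpl3 at -0.35 (SE 0.11), while Sox6 was higher at 0.31 (SE 0.10). Ceruloplasmin (Cp), at 0.73 (SE 0.19), Ggta1 at 0.81 (SE 0.21) and Fbln5 at 0.85 (SE 0.25) were the reactive glia genes that passed over the list alone in that comparison. Among astrocyte markers, Aldh1l1 at 0.36 (SE 0.08) and Clu at 0.35 (SE 0.09) passed, and among genes of the unfolded protein response Pdia4 at 0.34 (SE 0.09) and Calr at 0.22 (SE 0.06).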
